A study of Mus musculus with 9 samples.

How the data were processed

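RNA sequencing of wild-type mouse tissue labelled "brain ctx" was analysed, taken from the virus-infected centre 10 days after stereotaxic injection, in 9 libraries, with 3 each of the groups PBS, LowDose and HighDose. The amounts behind LowDose and HighDose were not used here.

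Estimated counts per gene were deposited by the authors for each library, made on mouse build mm10, with edgeR and DESeq2 named in the processing notes without a role. FPKM values per gene and library were deposited beside them, that is, counts divided by transcript length and library total, per the file headers. The aligner, the counter and the rule that chose the listed genes are not given in the sources used here. Of the count values, 7.66% to 14.0% per library were not whole, and counts were rounded to whole numbers first.

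The table holds 1710 genes, and a check on the FPKM values found that each differs at least 2-fold between at least 1 pair of group means (smallest log2 value 1.0008). Column sums are therefore not depths, and adjustment for multiple testing covers the listed genes only. Library totals were recovered from count, FPKM and transcript length as the median over 23 to 68 genes with a single transcript in GENCODE M21, FPKM of at least 5, at least 100 counts and length of at least 600 bases, with a scatter of 0.0113% to 0.0448% of the total. A floor of 3 counts lies at 0.126 to 0.164 CPM in these libraries. TMM scaling was chosen before the data were examined. After the choice of the listed genes was found in the values, library totals, also considered before the data were examined, became the main scaling, and TMM was run as an alternative, since it takes most genes as unchanged.

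Genes were filtered with filterByExpr (minimum count 10), which left 1583. Groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) in 1 model of the 3 groups, with HighDose against PBS, LowDose against PBS and HighDose against LowDose as contrasts, the Benjamini-Hochberg adjustment and a threshold of 0.05. Values after ± are SE for log2 changes and SD over 3 libraries for CPM. The SE was derived as the size of the log2 change over the square root of F, and is approximate, above all for genes near 0 counts. Of 47 gene lists fixed before the data were examined, the 28 with at least 5 tested members were tested with camera (preset correlation 0.01, log2 CPM with a prior count of 2), with camera at an estimated correlation and with fry. List levels per library used a pseudocount of 0.5 CPM. Genes at 0 counts in the reference group are given as "at least" a ratio over 3 counts, and genes at 1 to 3 counts as a ratio with a 95% counting interval. Of the listed gene identifiers, 1704 were found in GENCODE M21.

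Genes were named by a rule fixed before the data were examined. In HighDose against PBS these were the 10 highest and 10 lowest log2 changes among called genes with mean CPM of at least 1 and no overlap between the libraries of the groups, leaving out unnamed gene models and immunoglobulin or T cell receptor segments, then the 2 members with the smallest p of each list that passed, and 17 genes whatever their values. The other comparisons took 5 and 5 and the same 17 genes. Others are named only as the highest or lowest of a list or as members of a count of 5 or fewer, and are said to be chosen after their values were seen. Results for some genes that fall under the rule or its exceptions are not reported here.

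Alternatives were TMM, DESeq2 1.42.0 size factors and the sum of listed counts as scaling, no filter, a stricter filter (1 CPM in 3 libraries), the Wald test of DESeq2, limma-voom with sample weights, only the groups compared, a block for the replicate number, a 2-fold threshold and leaving out each library. Chosen after seeing the data were library totals without the listed genes, adjustment over all 55536 annotated genes and the level of the Striatum list as a covariate. The pipeline was tested on simulated data, with every group at the PBS level before changes were added, and 1245 genes passed the filter there. Of genes changed by 1 on the log2 scale it recovered 63.5%, 60.8% and 73.2% in the 3 comparisons, with 4%, 2.29% and 4.59% false calls. In counts simulated with most genes changed, a true median change of 1.89 came back as 1.91 with library totals. TMM gave 0.01 at a true median of 1.72. The library totals were used to make these counts. This therefore shows how the scalings behave, and not which is right for the real libraries. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.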

Results

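RNA of mouse brain tissue labelled "brain ctx" was sequenced 10 days after a stereotaxic injection, in 3 groups of 3 libraries each, labelled PBS, LowDose and HighDose. PBS is a buffered salt solution. The series title names adeno-associated virus (AAV), a small DNA virus used to carry genes into cells, and innate immunity through cGAS, an enzyme that senses DNA in the cytoplasm, and its partner STING. The comparisons ask what each dose changed against PBS and how the doses differed. Library totals were 18.3, 20.7 and 21.7 M for PBS replicates 1 to 3, 23.7, 22.2 and 18.7 M for LowDose, and 22.9, 20.9 and 23.1 M for HighDose (M, 1e6 reads or read pairs). Whether the 3 libraries of a group come from separate animals is not given in the sources used here, so n, SD, SE and p refer to libraries.

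The deposited table lists 1710 genes, and each of the 1710 differed at least 2-fold in mean FPKM between at least 1 pair of groups. The listed genes held 1.57% ± 0.0377 (SD, n = 3) of the counts of the PBS libraries, 1.36% ± 0.0206 of LowDose and 5.05% ± 1.08 of HighDose, where replicates 1 to 3 had 3.90%, 5.21% and 6.04%. A total of 1583 genes passed the low-count filter and were tested. Since the genes were listed for a difference between groups, counts of changed genes describe the listed genes and not the transcriptome, and the tests of HighDose repeat part of that choice. Lists of pan-neuronal, cortical excitatory neuron, synapse, ion channel, oxidative phosphorylation, mitochondrial and ribosomal genes had 0 tested members, and Tbk1, Irf3, Rbfox3 and Slc17a7 were not analysed here. Other lists were tested in part, such as 19 of 29 cGAS-STING members, 19 of 28 for Toll-like receptors, 7 of 20 for homeostatic microglia and 10 of 24 for oligodendrocytes. Of the type I interferon-stimulated genes 54 of 56 were tested. Counts of members that rose or fell cover the tested members only.

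Genes induced by type I interferon, the antiviral cytokine family, were far above their PBS level in HighDose. All 54 tested members of that list rose, with a median log2 change of 5.92, which was 4.02 above the median of all tested genes. Isg15, a ubiquitin-like protein that is attached to other proteins, went from 1.55 ± 0.851 counts per 1e6 of the library total (CPM) in PBS to 215 ± 62.2 CPM in HighDose (SD, n = 3 each), a log2 change of 7.10 ± 0.34 (SE). Irf7, a transcription factor that drives interferon genes, rose by 6.19 ± 0.29 on the log2 scale, Oasl2, an antiviral protein related to oligoadenylate synthetases, by 6.74 ± 0.29, and Mx1, an antiviral GTPase, by 9.71 ± 0.42. Ifnb1, which encodes interferon beta, had 0 counts in the PBS and LowDose libraries and 57 counts over the HighDose libraries (0.836 ± 0.504 CPM), at least 17.2-fold above PBS when PBS is set at a floor of 3 counts over the group. Ifnb1 did not pass the low-count filter and was not tested.

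Sensors of foreign DNA and RNA rose with them. Of the 19 tested members of the cGAS-STING list, 18 rose, with a median log2 change of 5.57 (3.67 above that of all tested genes). Cgas rose from 1.17 ± 0.195 to 5.12 ± 1.89 CPM (log2 2.12 ± 0.36, adjusted p = 1.35e-06), and Sting1 from 4.10 ± 0.522 to 17.1 ± 2.63 CPM (2.06 ± 0.26, adjusted p = 1.50e-09). The larger values of the list came from interferon-inducible nucleic acid sensors, among them Zbp1 at 8.34 ± 0.35, Ifi204 at 7.89 ± 0.34 and Ifi206 at 9.15 ± 0.43. All 9 RIG-I-like receptor list members rose (median 4.87, 2.97 above all tested genes), with the RNA helicase Rigi at 5.50 ± 0.27 and its relative Ifih1 at 5.29 ± 0.28. Of 19 Toll-like receptor list members 18 rose (median 2.30, 0.40 above all tested genes), with Tlr2, a receptor of bacterial lipoproteins, at 3.998 ± 0.32. All 23 NOD-like receptor and inflammasome list members rose (median 2.93, 1.03 above all tested genes), with Nlrp3, a scaffold of the inflammasome, at 1.83 ± 0.42. Scaled by TMM within the listed genes, Cgas stood at 0.36 (adjusted p = 0.213), Sting1 at 0.33 (0.0885) and Nlrp3 at 0.09 (0.813), and these calls were lost.

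Cgas (ENSMUSG00000032344) lies on chromosome 9 at 78430526 to 78443237 on the minus strand of mm10 in GENCODE M21, and Sting1 (ENSMUSG00000024349) on chromosome 18 at 35733679 to 35740554, minus strand. Isg15 (ENSMUSG00000035692) lies on chromosome 4 at 156199424 to 156200818, minus strand, and Irf7 (ENSMUSG00000025498) on chromosome 7 at 141262706 to 141266481, minus strand. Drd2 (ENSMUSG00000032259), described with the striatal genes, lies on chromosome 9 at 49340627 to 49408177, plus strand. Counts are of whole genes, over all annotated exons as far as the counting covered them.

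Antigen presentation and chemokine genes were also higher in HighDose. Of 32 interferon gamma-induced GTPases and targets 31 rose (median 5.71), among them the chemokine Cxcl10 at 9.28 ± 0.39 and the guanylate-binding protein Gbp6 at 6.72 ± 0.29. The 1 member that fell was Ido1, an enzyme of tryptophan breakdown that is also on the Striatum list, at -1.42 ± 0.40, chosen after its values were seen. All 23 members of the MHC class I list rose (median 3.94), with H2-Q7 at 7.50 ± 0.35 and Nlrc5, the transactivator of class I genes, at 6.73 ± 0.31. All 14 MHC class II members rose (median 3.83), the highest being H2-Eb1 at 5.03 ± 0.33, chosen after its values were seen. All 29 cytokine and chemokine members rose (median 3.94), with Cxcl9 at 7.45 ± 0.37. All 17 complement members rose as well (median 2.53, 0.63 above all tested genes). The 17 NF-kB members rose too, but their median of 1.81 was -0.09 relative to all tested genes and 0.04, 0.11 and 0.11 in the scalings within the listed genes. Gbp6, Ifi204, Ly6c2, H2-Q7, Ifi206 and Mx1 belong to families of similar genes and had counts that were not whole in 8, 7, 9, 3, 3 and 3 libraries, so the reads could be split between relatives and their values are uncertain.

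Most tested genes on the lists of lymphocytes and of other immune cells, several of them close to 0 in PBS, were higher in HighDose. Which cells made these transcripts was not measured. All 28 tested members of the T cell list rose (median 5.03, or 4.96 with genes at 0 in PBS set at their lower bound). Cd3e, a part of the T cell receptor complex, had 2 counts over the PBS libraries and 106 over HighDose, a ratio of 48.1 (95% counting interval 12.996 to 402), and Cd8a, a marker of cytotoxic T cells, went from 3 to 234 counts, a ratio of 70.8 (23.9 to 346). Cd69, an early activation marker, had 1 count in PBS and 587 in HighDose (ratio 533, interval 95.3 to 21085), and Il2rb, a receptor chain for interleukin 2, rose by 5.32 ± 0.35. All 20 cytotoxic effector and NK cell list members rose (median 6.23, or 5.25 with lower bounds), with the protease granzyme B (Gzmb) at 8.57 ± 0.45 and the chemokine Ccl5 at 8.45 ± 0.43. Of 9 monocyte and border macrophage list members 8 rose, led by Ly6c2 at 9.30 ± 0.39, and Cd163, a macrophage scavenger receptor, fell (-1.59 ± 0.49), chosen after its values were seen. All 8 dendritic cell members rose (median 4.01). Other genes with the highest values were Ms4a4c, with 2 counts in PBS (ratio 1370, interval 379 to 11321, uncertain since counts were not whole in 2 libraries), Slfn4 at 9.26 ± 0.42, Slfn1, with 2 counts in PBS (ratio 647, interval 179 to 5350), and Cxcl11, with 1 count in PBS (ratio 793, interval 142 to 31341). Gpr141 and Serpina3f had 0 counts in PBS and were at least 123-fold and at least 100.5-fold higher in HighDose.

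Among glial genes, all 27 reactive microglia list members rose (median 3.64), with the Fc receptor Fcgr4 at 6.21 ± 0.40 and Ms4a6c at 5.74 ± 0.32. Aif1, which encodes the microglial marker IBA1, rose by 2.27 ± 0.28. Of 7 homeostatic microglia members 4 rose and 3 fell. Olfml3 rose by 1.32 ± 0.22, while P2ry12, an ADP receptor of resting microglia, fell from 38.3 ± 4.14 to 19.5 ± 2.99 CPM (log2 -0.97 ± 0.22, adjusted p = 9.04e-05), and Fcrls (-1.38 ± 0.23) and Gpr34 (-1.07 ± 0.25), both chosen after their values were seen, fell too. Olfml3 turned to -0.41, -0.35 and -0.34 when scaled within the listed genes by TMM, DESeq2 size factors or the listed sum. All 33 reactive astrocyte members rose (median 2.56), the highest being the chemokine Cxcl10 at 9.28 ± 0.39. Gfap, the intermediate filament of astrocytes, rose from 126 ± 17.3 to 454 ± 80.0 CPM (1.85 ± 0.23, adjusted p = 1.27e-09, but 0.10 with adjusted p = 0.614 under TMM). Of 10 oligodendrocyte and myelin members 6 fell, the lowest being the myelin protein gene Mal at -1.13 ± 0.21 (chosen after its values were seen), and 4 rose, among them Apod, a lipid carrier, at 2.22 ± 0.24 and the protease Klk6 at 2.20 ± 0.27 (0.44 with adjusted p = 0.0548 under TMM, where its call was lost).

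**Figure D1:**
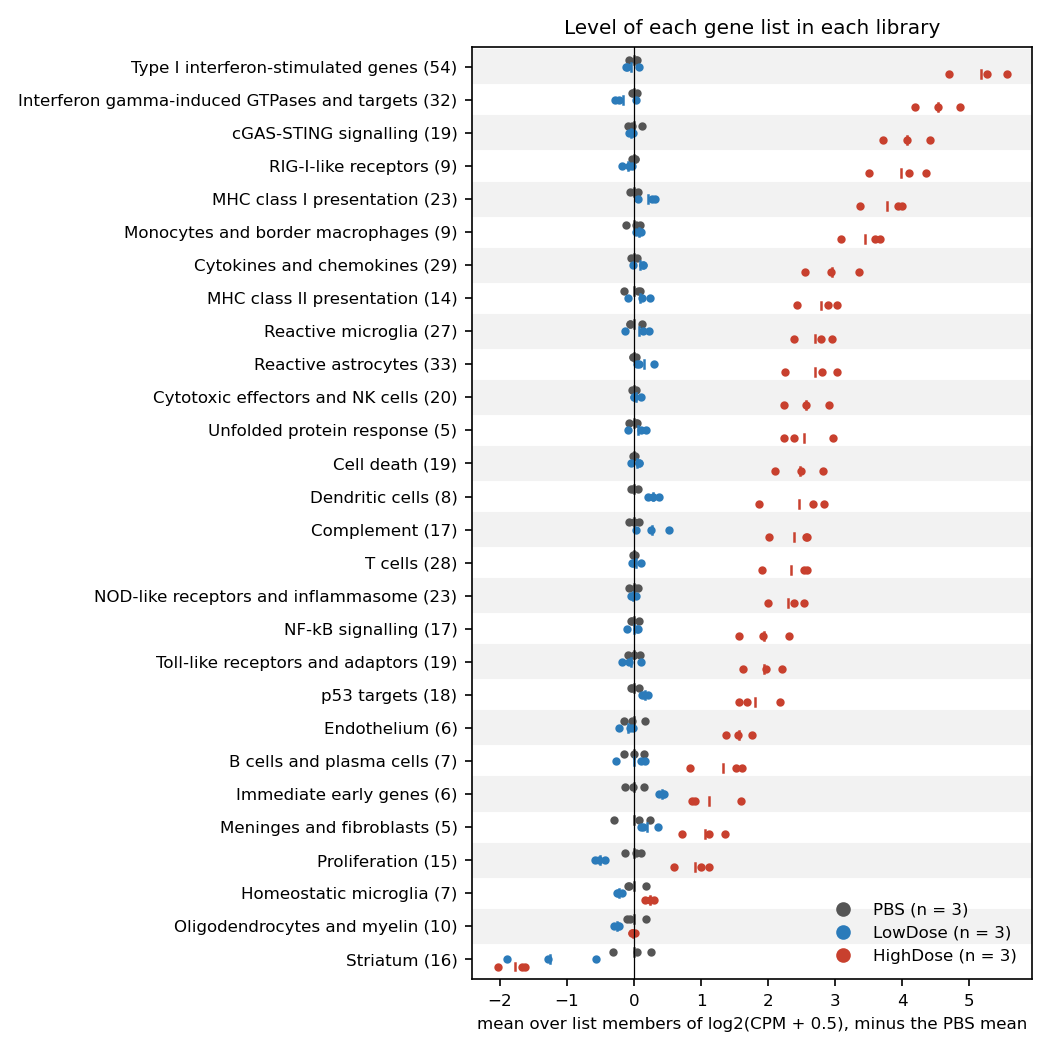
Level of each tested gene list in each library, as the mean over its tested members (number in brackets) of log2(CPM + 0.5) minus the PBS mean. Points are libraries and short lines group means (n = 3 per group). HighDose lies to the right of PBS for most lists and to the left for the Striatum list, where LowDose also lies to the left, at -0.57, -1.29 and -1.90.

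Genes marking the striatum, the region under the cortex that holds medium spiny neurons, were lower in HighDose. All 16 tested members of the list fell (median log2 -1.85). Drd2, the dopamine D2 receptor, fell from 36.6 ± 6.93 to 6.14 ± 1.97 CPM (log2 -2.57 ± 0.29, adjusted p = 1.37e-10), and Adora2a, the adenosine A2a receptor, from 54.1 ± 11.3 to 9.64 ± 2.37 CPM (-2.49 ± 0.31). Syndig1l (-2.93 ± 0.31) and the homeobox factor Six3 (-3.48 ± 0.50) fell most within the list. The other genes among the 10 lowest named by the rule were Slc10a4, a vesicle protein of cholinergic and monoaminergic neurons (-3.89 ± 0.57), Lrrc10b (-2.83 ± 0.29), Serpina9 (-2.70 ± 0.37), Sh3rf2 (-2.63 ± 0.36), the choline transporter Slc5a7 (-2.46 ± 0.43) and Chat, the enzyme that makes acetylcholine (-2.41 ± 0.47). The level of the Striatum list also differed within the PBS group, at 0.05, 0.26 and -0.31 in replicates 1 to 3 relative to the PBS mean. HighDose replicates 1 to 3 lay at -1.63, -1.67 and -2.04, and LowDose replicate 3 lay among them at -1.90. How much striatum each piece of tissue held was not measured, so the fall in HighDose cannot be told apart from uneven pieces.

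The list test (camera, which compares a list with the other tested genes) passed for 12 of 28 lists in HighDose against PBS. It passed upward for the type I interferon-stimulated genes (adjusted p = 3.88e-09), interferon gamma targets (8.66e-05), MHC class I (0.000531), cGAS-STING (0.0110), cytotoxic effectors (0.0110), T cells (0.0123), cytokines (0.0176), RIG-I-like receptors (0.0350) and reactive microglia (0.0353, but 0.0545 without HighDose replicate 1). For these 9 lists adjusted p = 0.750 with an estimated correlation. It passed downward for the Striatum list (1.03e-23, and adjusted p = 0.311 with an estimated correlation), oligodendrocytes (4.59e-05, and adjusted p = 0.311) and homeostatic microglia (0.0194, and adjusted p = 0.526). The oligodendrocyte list had a median of -1.01 and a mean of 0.01, and the homeostatic microglia list a median of 0.89 and a mean of 0.25, against the direction of its test, with a median below 0 in the scalings within the listed genes (-0.84 under TMM). It did not pass for NOD-like receptors (0.0613), MHC class II (0.0632), reactive astrocytes (0.0531), complement (0.167), NF-kB (0.263), dendritic cells (0.268), Toll-like receptors (0.302) and monocytes (0.317), all with an upward sign. Under TMM, DESeq2 size factors and the listed sum, 5 of these lists passed: NOD-like receptors (0.0189, 0.0180 and 0.0182), MHC class II (0.0118, 0.0126 and 0.0134), reactive astrocytes (0.0189, 0.0180 and 0.0182), monocytes (0.0327, 0.0370 and 0.0361) and dendritic cells (0.0423, 0.0456 and 0.0438). Nor did it pass for B cells (0.946), endothelium (0.893), immediate early genes (0.611) and meninges (0.440), with a downward sign against medians of 3.29, 1.99, 1.47 and 1.58, of which the last 3 were -0.62, -0.30 and -0.21 under TMM. Leaving out PBS replicate 1 or 3 let the NOD-like receptors pass (0.0424 and 0.0394), and the reactive astrocytes passed without PBS replicate 2 (0.0483) or 3 (0.0394), LowDose replicate 2 (0.0454) or HighDose replicate 1 (0.0442). In each of the 28 lists, the number of members passing adjusted over the list alone was the same as over all genes tested. Lists share members, so lists that passed are not all separate results. Cxcl10, for example, was the highest member of the interferon gamma, cytokine and reactive astrocyte lists.

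Over the 1583 tested genes, 1366 rose and 169 fell in HighDose against PBS at an adjusted p threshold of 0.05 (edgeR quasi-likelihood test), and 1269 and 158 of them by at least 2-fold. In 1359 genes every HighDose library was above every PBS library and in 163 below. Chance gives 10% in both directions together for genes not chosen by their difference. Here 1581 of the 1710 listed genes already differed at least 2-fold in mean FPKM between these groups, so the 10% is no baseline for them. Scaled within the listed genes by TMM, DESeq2 size factors or the listed sum, which take most listed genes as unchanged, the median of all tested genes moved from 1.90 to -0.03, 0.04 and 0.04, and the calls to 504 up and 478 down, 526 and 455, and 524 and 453. With the level of the Striatum list as a covariate, chosen after seeing the data, 656 rose and 30 fell. The covariate is built from the 16 striatal genes and differs between the groups, so that 0 of these genes passed follows from its construction.

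**Figure D2:**
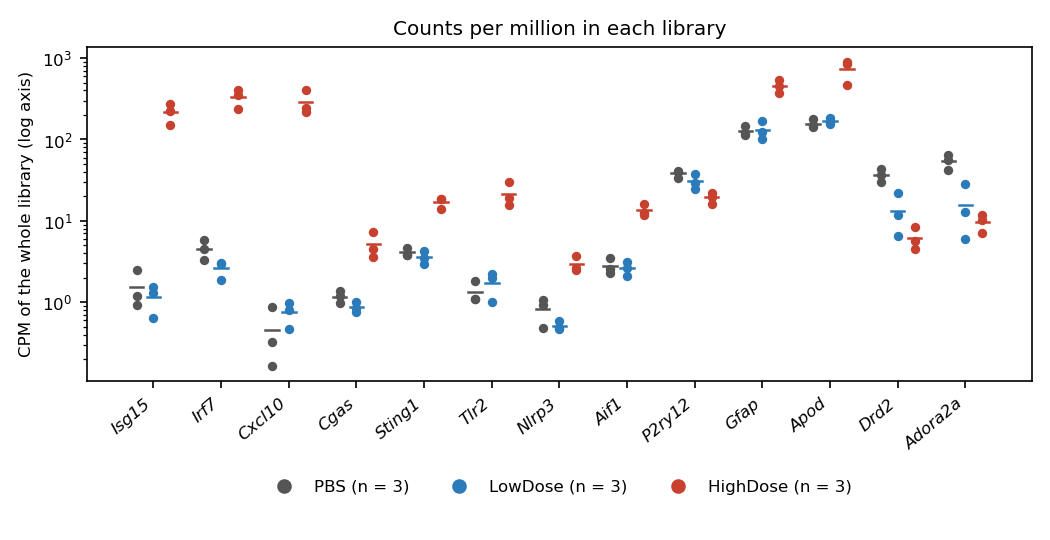
CPM of the whole library (log axis) of named genes in each library. Points are libraries and lines group means (n = 3 per group). Isg15, Irf7 and Cxcl10 lie at 5.76 CPM or below in PBS and LowDose and at 149 CPM or above in HighDose, while Drd2 and Adora2a are lower in LowDose and HighDose than in PBS.

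In LowDose, type I interferon-stimulated genes lay near their PBS level. The 54 type I interferon-stimulated genes had a median log2 change of -0.03 against PBS (0.02, 0.00 and 0.18 in the scalings within the listed genes), and 0 passed the test (4 at an unadjusted p under 0.05 in edgeR, and 0 by DESeq2 or limma-voom). Isg15 was at 1.15 ± 0.457 CPM against 1.55 ± 0.851 in PBS (log2 -0.41 ± 0.34, adjusted p = 0.787), Cxcl10 at 0.751 ± 0.266 against 0.453 ± 0.371 (0.69 ± 0.44, adjusted p = 0.629) and Irf7 at 2.62 ± 0.624 against 4.52 ± 1.25 (-0.80 ± 0.27, adjusted p = 0.104, but -0.98 with 0.0447 without PBS replicate 1). The log2 values of Cgas (-0.43 ± 0.40), Sting1 (-0.21 ± 0.26), Tlr2 (0.35 ± 0.34), Nlrp3 (-0.69 ± 0.47), Gfap (0.06 ± 0.22), Aif1 (-0.09 ± 0.29) and P2ry12 (-0.32 ± 0.22) did not pass either, with adjusted p from 0.655 to 0.962. Cd3e and Cd8a had 3 counts each over the LowDose libraries, against 2 and 3 in PBS. The 32 interferon gamma-induced GTPases and targets had a median of -0.23, and 2 of them, Ido1 (-1.72 ± 0.41), which is also on the Striatum list, and Tgtp1 (-1.47 ± 0.32, chosen after its values were seen), fell, with 7 at an unadjusted p under 0.05 and 2 adjusted over the list alone. The list did not pass (adjusted p = 0.277), but passed downward without LowDose replicate 2 (0.0353), and the call of Tgtp1 was lost without PBS replicate 3 (0.0560).

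Striatal genes fell in LowDose. Of the 34 genes that fell, 12 were among the 16 striatal list members (median of the list -1.18), and 16 passed adjusted over the list alone. Adora2a fell from 54.1 ± 11.3 to 15.6 ± 11.3 CPM (log2 -1.79 ± 0.30, adjusted p = 0.000269), Syndig1l by 1.62 ± 0.29 and Drd2, chosen after its values were seen, to -1.45 ± 0.28 on the log2 scale. Lrrc10b (-1.65 ± 0.27), Serpina9 (-1.80 ± 0.35) and Ido1 (-1.72 ± 0.41) were the others of the lowest values named by the rule. The 3 LowDose libraries lay at -0.57, -1.29 and -1.90 for the mean of the list. The call of Ido1 was lost without PBS replicate 2 (adjusted p = 0.102) or LowDose replicate 2 (0.0560) or 3 (0.0546). Under TMM, DESeq2 size factors and the listed sum the change of Adora2a was -1.72, -1.74 and -1.58 and its call was lost (adjusted p = 0.128, 0.121 and 0.0885), as were those of Syndig1l (0.133, 0.123 and 0.0950), Drd2 (0.155, 0.144 and 0.114), Lrrc10b (0.117, 0.105 and 0.0805) and Ido1 (0.0894, 0.0815 and 0.0617), and that of Serpina9 under the first scalings alone (0.0602 and 0.0536). The log2 changes under TMM stayed near the reported ones, at -1.55 for Syndig1l, -1.38 for Drd2, -1.59 for Lrrc10b, -1.65 for Ido1 and -1.73 for Serpina9.

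A smaller number of genes rose in LowDose. Sgk1, a kinase induced by glucocorticoids, rose from 66.8 ± 10.99 to 160 ± 7.58 CPM (log2 1.26 ± 0.21, adjusted p = 0.000269), Cdkn1a, the cell cycle inhibitor p21, by 1.03 ± 0.23 (0.00604) and Fosb, an immediate early transcription factor, by 1.21 ± 0.28 (0.00824). Gimap3, a GTPase of lymphocytes, had 1 count in PBS and 17 in LowDose (ratio 15.9, interval 2.499 to 666, adjusted p = 0.0344), and this call was lost without PBS replicate 1 (0.0737) or 3 (0.0962) or LowDose replicate 2 (0.227). Cst7, the protease inhibitor cystatin F, rose by 1.76 ± 0.49 (0.0371), but stood at 0.89 (adjusted p = 0.648) without LowDose replicate 3, and its call was also lost without PBS replicate 1 (0.0527) or HighDose replicate 1 (0.0782) or 3 (0.0666). In the same scalings Sgk1 and Cdkn1a kept their calls, and those of Fosb (0.0966, 0.0973 and 0.0529), Gimap3 (0.117, 0.120 and 0.0617) and Cst7 (0.157, 0.144 and 0.0950) were lost, although their log2 changes were no smaller (Fosb 1.26, 1.25 and 1.43, Gimap3 3.796, 3.78 and 3.95, Cst7 1.80, 1.79 and 1.98).

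Among the 10 oligodendrocyte and myelin list members, Sgk1 rose and Mal (-0.78 ± 0.21) and Tspan2 (-0.71 ± 0.21) fell in LowDose. Mal and Tspan2 were chosen after their values were seen. The list did not pass (median -0.60, adjusted p = 0.102), and 7 members passed adjusted over the list alone. Leaving out any 1 of the 6 PBS and LowDose libraries ended the calls of Mal (adjusted p from 0.0545 to 0.176) and Tspan2 (0.0784 to 0.239, and 0.0647 without HighDose replicate 2). Under TMM, DESeq2 size factors and the listed sum both calls were lost as well (0.152, 0.143 and 0.162 for Mal, 0.111, 0.0971 and 0.125 for Tspan2), with log2 changes of -0.73, -0.74 and -0.57 for Mal and -0.67, -0.68 and -0.51 for Tspan2. The proliferation list had a median of -0.85, with 0 of 15 members passing in edgeR over all genes tested (7 at an unadjusted p under 0.05, 0 by DESeq2 and 3 by limma-voom) and 5 adjusted over the list alone. Its lowest member was the mitotic kinase Aurkb at -1.74 ± 0.61 (adjusted p = 0.130), chosen after its values were seen.

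The list test passed for 9 of 28 lists in LowDose. Downward were the Striatum list (adjusted p = 2.85e-15) and the proliferation list (7.29e-07), for both of which adjusted p = 0.709 with an estimated correlation. Upward were MHC class I (median log2 0.20, adjusted p = 0.000998), dendritic cells (0.41, 0.00382), complement (0.40, 0.00909), reactive astrocytes (0.15, 0.0373), immediate early genes (0.44, 0.0373), p53 targets (0.13, 0.0373) and cytokines (0.34, 0.0396), for which adjusted p = 0.967 with an estimated correlation. Of their members over all genes tested, Cd209a rose in the dendritic cell list, Ptgs2 in the astrocyte list, Fosb and Ptgs2 among the immediate early genes and Cdkn1a among the p53 targets, while 0 passed in the MHC class I, complement and cytokine lists (2, 3 and 2 at an unadjusted p under 0.05 in edgeR, 0 in each by DESeq2, and 0, 1 and 1 by limma-voom). Cd209a and Ptgs2 were chosen after their values were seen. Adjusted over the list alone, 1, 1, 3 and 2 members passed in the first 4 of these lists. Without PBS replicate 1 only 4 lists passed.

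Several of these upward calls depended on the scaling or on single libraries. Under TMM, DESeq2 size factors and the listed sum the calls of dendritic cells (adjusted p = 0.161, 0.145 and 0.288), cytokines (0.171, 0.153 and 0.394) and immediate early genes (0.0790, 0.0742 and 0.0913) were lost, as was that of reactive astrocytes under the listed sum (0.0549). The medians were 0.37, 0.36 and 0.53 for dendritic cells, 0.38, 0.37 and 0.54 for cytokines and 0.49, 0.48 and 0.65 for immediate early genes in these scalings. Complement did not pass without PBS replicate 1 (adjusted p = 0.0691) or LowDose replicate 2 (0.124). Its highest member Cfb, complement factor B, chosen after its values were seen, was at 1.01 ± 0.35 (0.112) and passed without PBS replicate 3 (0.0239), LowDose replicate 1 (0.000680) or 3 (0.00455) or HighDose replicate 2 (0.0414). The cytokine list did not pass without PBS replicate 1 (0.0735), 2 (0.0772) or 3 (0.125), LowDose replicate 2 (0.154) or 3 (0.165) or HighDose replicate 1 (0.0800). Reactive astrocytes did not pass without PBS replicate 1 (0.0836) or 2 (0.102) or LowDose replicate 1 (0.0503) or 2 (0.188). The immediate early genes did not pass without PBS replicate 1 (0.106) or 2 (0.0867), LowDose replicate 1 (0.160) or 3 (0.0511) or HighDose replicate 1 (0.0532), and the p53 targets without PBS replicate 1 (0.0836) or 3 (0.0832) or LowDose replicate 1 (0.191). Cd209a lost its call without PBS replicate 2 (0.139) or 3 (0.120), LowDose replicate 2 (0.0560) or HighDose replicate 3 (0.0611). Ptgs2 lost its call without any 1 of the PBS libraries (0.121, 0.179 and 0.0962), LowDose replicate 1 (0.0757) or 3 (0.213) or HighDose replicate 2 (0.0568).

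The test gave 7 genes that rose and 34 that fell in LowDose against PBS (edgeR, 185 genes at an unadjusted p under 0.05), with 79 calls without LowDose replicate 1 and 26 without LowDose replicate 2. Of the 1710 listed genes, 1581 differed at least 2-fold in mean FPKM between HighDose and PBS, and 288 between LowDose and PBS. These counts therefore describe LowDose within genes listed mostly for HighDose, and not the whole LowDose response. Scaled by TMM, DESeq2 size factors or the listed sum, 3 rose and 2 fell, 3 and 2, and 8 and 2, limma-voom called 17 up and 79 down, and with the Striatum list as a covariate 1 rose and 2 fell. On data simulated for this comparison the test recovered 60.8% of genes changed by 1 and 95.2% of those changed by 2 on the log2 scale. In that simulation 79 genes were changed by 1 and 84 by 2, and every group started at the PBS level. There 1245 genes passed the filter, in place of 1583. The percentages therefore say little about genes close to 0 in PBS, among them several immune genes, and may not hold with fewer changed genes.

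**Figure D3:**
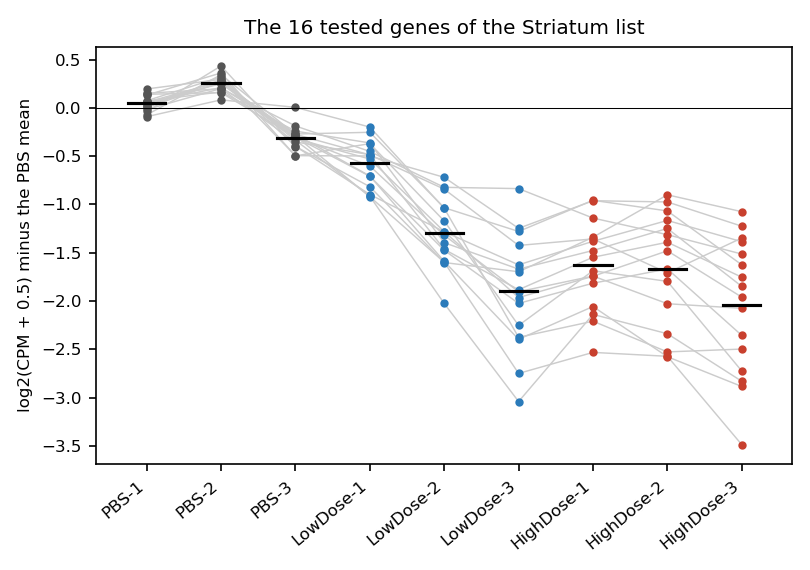
Level of the 16 tested genes of the Striatum list in each of the 9 libraries, as log2(CPM + 0.5) minus the PBS mean of the gene. Points are genes, thin lines join the same gene across libraries and black bars are means over the genes, which run from 0.26 in PBS replicate 2 to -2.04 in HighDose replicate 3.

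The doses differed from each other in the same immune groups when tested directly. All 54 type I interferon-stimulated genes were higher in HighDose than in LowDose (median log2 5.97), as were all 19 cGAS-STING members (5.78), all 28 T cell members (4.86) and all 27 reactive microglia members (3.29). Isg15 differed by 7.51 ± 0.35, Irf7 by 6.99 ± 0.31, Cxcl10 by 8.59 ± 0.37, Tlr2 by 3.65 ± 0.31, Cgas by 2.55 ± 0.37, Nlrp3 by 2.52 ± 0.44, Aif1 by 2.36 ± 0.28, Sting1 by 2.27 ± 0.26 and Gfap by 1.79 ± 0.23. Klrk1, the NK and T cell receptor NKG2D, had 0 counts in LowDose and was at least 168-fold higher in HighDose, and Ifnb1 was at least 18.4-fold higher. The other highest values were those of Slfn4 (9.99 ± 0.44), Ms4a4c (9.39 ± 0.45), Ifi205 (8.92 ± 0.46) and Gbp10 (8.87 ± 0.41), of which Ifi205 and Gbp10 had counts that were not whole in 7 and 8 libraries and are uncertain. Cd3e and Cd8a, at 3 counts each in LowDose, had ratios of 34.2 (interval 11.4 to 168) and 75.5 (25.5 to 369).

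Lower in HighDose than in LowDose were Slc10a4 (-2.44 ± 0.59), Rpe65, an enzyme of the retinoid cycle (-1.89 ± 0.42), Btbd17 (-1.54 ± 0.27), Hes5, a transcription factor downstream of Notch (-1.48 ± 0.33), and Aldh1a3, which makes retinoic acid (-1.37 ± 0.39). P2ry12 was lower by -0.65 ± 0.22 (adjusted p = 0.00554), a call lost without LowDose replicate 1 (-0.48, adjusted p = 0.0628). Of the 16 striatal genes 10 were lower in HighDose than in LowDose (median -0.61). All 15 proliferation members were higher (median 1.86, but -0.05 when scaled by the listed sum).

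The direct test of the doses gave 1394 genes higher and 112 lower in HighDose among 1583 tested (edgeR). In the scalings within the listed genes the median of all tested genes moved from 1.88 to -0.05, 0.03 and -0.15, the calls became 475 higher and 481 lower, 497 and 447, and 454 and 525, and Nlrp3 lost its call (0.74, adjusted p = 0.0746 under TMM), as did Gfap (0.01, adjusted p = 0.967), which turned to -0.10 under the listed sum, and Sting1 under the listed sum alone (0.40, 0.0619). The list test passed for 13 of 28 lists, 10 upward and 3 downward. The upward lists had adjusted p from 7.75e-11 for the type I interferon-stimulated genes to 0.0495 for NOD-like receptors. With an estimated correlation 0 of the 13 held, the smallest adjusted p = 0.383 with an estimated correlation, and fry, which tests each list on its own, passed 26. The NOD-like receptors did not pass without LowDose replicate 3 (0.0510) or HighDose replicate 1 (0.0881) or 3 (0.0635), nor the reactive microglia without HighDose replicate 1 (0.0719) or 3 (0.0550). Downward were homeostatic microglia (0.0172, with a median of 1.12 and a mean of 0.48 above 0, and medians of -0.66, -0.59 and -0.76 in those scalings), oligodendrocytes (3.82e-05, median -0.27 and mean 0.28) and the Striatum list (1.27e-14). In each of the 28 lists, as many members passed adjusted over the list alone as over all genes tested.

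Of the 41 genes called in LowDose, 37 were called in the same direction in HighDose against PBS, 7 up and 30 down, and 2, Tgtp1 and Eomes, in opposite directions. Of all 1583 tested genes 1535 (96.97%) were called in HighDose against PBS. That a LowDose call was also a HighDose call therefore says little, and only the directions can differ from this share. Tgtp1, an interferon-induced GTPase with counts that were not whole in 9 libraries, was at -1.47 ± 0.32 in LowDose and 5.63 ± 0.29 in HighDose, and Eomes, a transcription factor of cytotoxic lymphocytes, at -3.89 ± 1.04 and 2.57 ± 0.56, both chosen after their values were seen. The LowDose call of Tgtp1 was lost without PBS replicate 3 (adjusted p = 0.0560) and in the scalings within the listed genes (0.0717, 0.0708 and 0.0617), and that of Eomes without PBS replicate 3 (0.0992) or LowDose replicate 1 (0.0618) or 2 (0.111) and with DESeq2 size factors (-4.04, 0.118). Independent lists of these sizes share 6.04 genes up and 3.63 down, so the 7 up lie near that number and the 30 down above it. How far the choice of listed genes adds to the 30 down was not tested. In 50 simulated pairs of unchanged groups with a shared simulated PBS group, 0 genes were shared. With no gene changed, few calls could arise there. This 0 therefore does not measure what shared controls or the choice of listed genes add to the real overlap. Across the 1583 genes, which are not independent replicates, the log2 changes of the doses had a covariance of 0.625, against 0.0613 in the simulated groups, a difference of 0.564, and a correlation of 0.376, against 0.506. With 3 PBS libraries the controls could not be split into separate sets for the doses, so the overlap includes what the shared controls add. The overlap was 22 genes without LowDose replicate 2, 68 without LowDose replicate 1, and 3, 3 and 4 in the scalings within the listed genes. Testing both dose contrasts together, 1583 of 1583 genes differed among the groups, which repeats the choice of the listed genes.

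**Figure D4:**
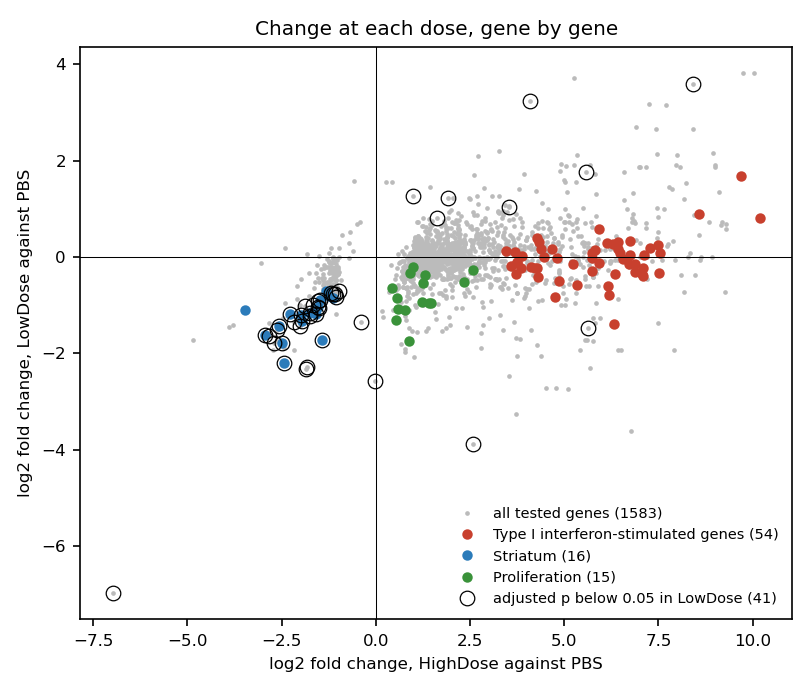
Log2 fold change of each of the 1583 tested genes in HighDose (x axis) and in LowDose (y axis) against PBS. Coloured points are the type I interferon-stimulated genes, which spread along the x axis near 0 on the y axis, the Striatum list, below 0 on both axes, and the proliferation list, with a median of 0.996 on the x axis (-0.74 under TMM) and -0.85 on the y axis. Rings mark the 41 genes called in LowDose.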

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

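The scalings, filters, tests and left-out libraries were planned. Library totals without the listed genes, adjustment over the annotation and the Striatum covariate were chosen after seeing the data. Gene counts were within 1.5 times the reported value under no filter, the stricter filter, the DESeq2 Wald test, only the groups compared, library totals without the listed genes and the 2-fold threshold. Unless a cause is given, the cause was not tested.

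Scaling within the listed genes by TMM, DESeq2 size factors or the listed sum takes most listed genes as unchanged. The calls in HighDose against PBS went from 1535 to 982, 981 and 977, those in HighDose against LowDose from 1506 to 956, 944 and 979, those for any difference from 1583 to 1010, 1006 and 1024, those in LowDose against PBS from 41 to 5, 5 and 10, and the overlap from 37 to 3, 3 and 4. Lists passing in HighDose against PBS went from 12 to 19, 19 and 19, and in LowDose with the listed sum from 9 to 5. Olfml3 reversed in HighDose against PBS, from 1.32 to -0.41, -0.35 and -0.34, and Gfap in HighDose against LowDose with the listed sum, from 1.79 to -0.10. In HighDose against PBS, a simulated median of 1.72 came back from TMM as 0.01, so TMM moves a shared change of most listed genes to near 0. Those counts were simulated from the library totals, so this cannot show that the totals are the right scaling. LowDose against PBS was not simulated this way. There Adora2a stood at -1.72 ± 0.46 under TMM, beside -1.79 ± 0.30, with 1409 genes tested in place of 1583, and the cause of the lost calls was not tested.

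In LowDose against PBS, limma-voom called 96 genes with an overlap of 76. Adjusting over the annotation left 8 genes and an overlap of 8, by its own construction. A block for the replicate number called 62. Nothing in the labels pairs the libraries by number, and deviations of same-number libraries correlated at -0.0208 to 0.182, against -0.186 to 0.146 for other numbers.

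With the Striatum list as a covariate, HighDose against PBS called 686, LowDose against PBS 3 and the overlap was 2. Since the covariate is built from the striatal genes, their own changes go towards 0 by construction. Reversed in HighDose against PBS were Adora2a to 0.27, Ido1 to 0.45, Sh3rf2 to 0.30 and Slc5a7 to 0.91, and in LowDose against PBS Cst7 to -0.21 and Drd2 to 0.0060.

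With an estimated correlation 0 lists passed in HighDose against PBS, 0 in LowDose against PBS and 0 in HighDose against LowDose. With fry, which tests a list against no change, 27, 0 and 26 passed, and lists that rose less than the other listed genes reversed. In HighDose against PBS these were homeostatic microglia (0.0103), B cells (0.000548), immediate early genes (0.00134), endothelium (4.10e-05), meninges (0.00255) and proliferation (0.000673). In HighDose against LowDose they were homeostatic microglia (0.000692), B cells (0.000509), immediate early genes (0.0126), oligodendrocytes (0.0596), endothelium (3.22e-05) and meninges (0.00629).

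Leaving out 1 library, calls ranged from 1504 to 1599 in HighDose against PBS, 26 to 79 in LowDose against PBS, 1463 to 1570 in HighDose against LowDose and 1543 to 1647 for any difference. The overlap ranged from 22 to 68, and lists passing from 12 to 14, 4 to 9 and 11 to 14. Where a group kept 2 libraries, the spread was pooled over the groups. Among single named genes, 1161 leave-one-out values kept their direction and side of the threshold, 48 lost and 6 gained a call, and 9 changed sign without a call. Depth limits genes near the floor of 3 counts, at 0.126 to 0.164 CPM.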

Other observations

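The lists of this part were fixed before the data were examined, the weighing of the striatal and proliferation patterns was chosen after the results were seen, and the regroupings of libraries were planned before.

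Cell stress genes were also higher in HighDose than in PBS, as were 1366 of the 1583 tested genes. All 19 tested cell death list members rose (median log2 2.84, 0.94 above all tested genes, camera adjusted p = 0.0613, but 0.0407, 0.0387 and 0.0381 under TMM, DESeq2 size factors and the listed sum). The highest was Zbp1 at 8.34 ± 0.35, which is also on the cGAS-STING list. Of 18 p53 targets 17 rose, with a median of 1.56 (camera adjusted p = 0.303). This median was -0.35 relative to all tested genes and -0.19 under TMM. The highest p53 target was the death receptor Eda2r at 5.20 ± 0.40. All 5 unfolded protein response members rose (median 2.07, 0.17 above all tested genes, adjusted p = 0.302), the highest being the stress factor Atf3 at 5.62 ± 0.33. Eda2r and Atf3 were chosen after their values were seen. The tested members were 19 of 33 on the fixed cell death list, 18 of 32 for p53 targets and 5 of 25 for the unfolded protein response. The others were not tested, so these values do not describe the whole lists.

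The proliferation list had 10 of 15 members that rose in HighDose (median 0.996, camera adjusted p = 0.467 with a downward sign). Under TMM, DESeq2 size factors and the listed sum its medians were -0.74, -0.71 and -0.68 and it passed downward (adjusted p = 0.0327, 0.0272 and 0.0320). The highest member was Mcm6, a part of the replicative helicase, at 2.59 ± 0.24, chosen after its values were seen. For the mean of the list, LowDose libraries lay at -0.59, -0.52 and -0.43 relative to the PBS mean and HighDose libraries at 0.60, 0.99 and 1.12.

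Striatal genes lower in LowDose than in PBS could come from pieces of tissue that held different amounts of striatum. If so, the genes of the list should move together within the PBS group, and 15 of 16 members shared the commonest rank order of the 3 PBS libraries, against a median of 5 and at most 11 in 1000 random sets. The random sets were matched on mean expression only. Genes that move together (estimated correlation 0.85) would share an order under other sources too, so this cannot decide. List levels ran from -0.31 to 0.26 in PBS and from -1.90 to -0.57 in LowDose. Dilution by incoming immune cells was excluded as the source, since T cell, cytotoxic and monocyte list members had a median LowDose change of 0.17, against 5.31 in HighDose. An effect of the vector on striatal neurons was not tested and remains open. For the fall of these genes in HighDose, different amounts of striatum in the pieces remain open too.

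The lower proliferation list in LowDose could have come from the choice of listed genes by their difference between the doses. Among the 7 of 15 members that differ 2-fold between HighDose and PBS the median LowDose change was -0.55, with 7 below 0. As low were 6 of 1000 random sets. The choice of listed genes does not account for the fall of these 7 members. For the other members it remains open, and it may have enlarged the list median of -0.85. The random sets were matched on mean expression only, while the members move together (estimated correlation 0.33), so the share of random sets is not a p-value.

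Regrouping the 6 libraries of a comparison into 3 and 3 gives 10 splits, which are too few to decide. The real split is 1 of the 10 in each case. It called 1535 genes in HighDose against PBS (highest other 0), 41 in LowDose against PBS (2) and 1506 in HighDose against LowDose (0), and 12, 9 and 13 lists (highest others 10, 6 and 8). For any difference among the groups, 1 of 100 drawn splits, the real one, called as many as 1583 genes (highest other 1544). All 1710 listed genes differed at least 2-fold between means of the real groups, so the real grouping was favoured in advance. These regroupings, and those into 3 and 3, therefore cannot tell how far the real grouping exceeds chance. For the overlap, 3 of 100 drawn labellings shared at least 37 calls, and the highest shared 1500.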
